A study of Mus musculus with 6 samples.

How the data were processed

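The study sorted haematopoietic stem and progenitor cells of C57BL/6 mice and sequenced single cells in 6 libraries, 1 per group. Per the labels' protocols, cells were lysed singly, RNA was reverse transcribed by a modified Smart-seq2 method, the cDNA was fragmented, the 3' ends were enriched with biotin primers and streptavidin beads, and libraries were sequenced on an Illumina HiSeq. The labels give polyA RNA and mice of 8 to 10 weeks for 4 libraries and total RNA and 8 weeks for the HSC2/MPP4 and CD48-negative HSC2 libraries, which were deposited as separate tables. Of the 4, the HSC1 and HPC1 libraries are labelled spleen although the series title speaks of bone marrow; tissue, gates and library cannot be separated. TopHat, HTSeq and the mm10 build are named by the submitters' processing notes, and their versions, the annotation, the cell filter, the normalization and any doublet removal are not given in the sources used here. The design text adds up to 324 cells in 7 populations, the joint table of the 4 libraries holds 322, and the 3 tables together hold 497. Column names give the library and a cell number only, so no cell was assigned to a gate or to the fractions P1 to P3 that the design text names, and the planned comparisons of those populations were not made.

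The deposited values are scores, not counts: within a gene they have mean 0 and SD 1 over all 497 cells, they go below 0, and they are capped at 10 (0.076% of values). The 2 later tables as deposited carry no gene names. Their lines were tied to the named table by the scaling itself, since 9901 uncapped genes have a joint mean within 1.1e-10 of 0 and a joint SD within 4.5e-11 of 1, whereas lines shifted by 1 give a median distance of 0.033 from 0. A total of 6 blank lines were dropped from the named table, which left 13278 genes.

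Counts were recovered from the scores. Cells without a gene lie on a plane spanned by an intercept and 4 cell covariates that had been regressed out, which fixes the covariates up to a linear map and lets the regression and scaling be undone. The recovered total count per cell is explained by the removed covariates with an R2 of 0.9999998, and the scale factor was taken as 10000 per cell. Covariates of 14 cells and the scale of 21 cells were solved again. Of 13278 genes, 198 had no plane and 1095 too few detecting cells, and 11985 were recovered. Of 1992806 recovered values up to 50, 100.0000% were whole numbers within 0.01. Genes that were not recovered include abundant ones found in nearly every cell, so the recovered genes hold 50.8 to 79.9% of a cell's total (median 60.3%), and CPM are of the recovered total count of a cell including the rest. A capped value gives a lower bound on a count, and 2282 recovered genes hold at least 1. The procedure was tested on simulated counts for HSC2/MPP4 over CD48-negative HSC2: 11952 of 11982 genes were recovered, 99.995% of uncapped counts exactly, and genes changed 2-fold and 4-fold (100 each) had recovered median log2 ratios of 0.895 and 1.84 against 0.883 and 1.84 in the drawn counts. The simulated genes were taken from those already recovered and were scaled by the model that the recovery assumes. The simulation therefore checks the computation, and neither the model nor the share of genes that can be recovered. The labels do not say whether molecular identifiers were used, so values are called counts.

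Levels are counts summed over the cells of a library per 1000000 counts (CPM). Shares of cells were taken after thinning each cell to 10000 counts, which left out 1 double-negative, 4 HSC1, 1 HPC1, 0 MPP2-containing, 8 HSC2/MPP4 and 20 CD48-negative HSC2 cells. A count of 0 was taken to allow up to 3 counts, which is 0.2 CPM in the MPP2-containing library and 1.08 in CD48-negative HSC2. Pooled sums weight deep cells: the deepest 10% of cells held 25.0% (HSC1) to 34.6% (CD48-negative HSC2) of a library's counts. Cells were neither clustered nor filtered, and no doublets were called.

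With 1 library per group no test was run. A gene list was described by the median log2 ratio of its members and by the percentile of that median among 10000 random lists of the same size, each member replaced by 1 of the 100 genes nearest in mean level; this describes these libraries and is not a test. Genes were named by a fixed rule: the 10 highest and 10 lowest by log2 ratio among genes counted in at least 25% of cells of 1 library and with detection in the same direction, leaving out predicted, mitochondrial and ribosomal protein symbols. Members of the fixed lists could also be named. The medians and counts cover every recovered member of a list, including some that are not reported here by name. The 21 lists were HSC, megakaryocyte-platelet, erythroid, granulocyte-monocyte progenitor, lymphoid progenitor, mast cell-basophil, mature neutrophil, macrophage-monocyte, mature B, T and NK cell, endothelial and stromal, S phase, G2/M phase, cell-cycle inhibitor and quiescence, ribosome biogenesis and Myc target, immediate early and dissociation stress, interferon response, MHC class II, mitochondrial respiration, glycolysis, RNA quality and sort surface genes. For RNA quality 2 members were recovered and no median was taken. Positions come from GENCODE M21 on GRCm38, the same build as mm10, matched by symbol for 284 of 284 genes looked up.

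The lists, the rule for named genes, the pseudocount and 1 set of alternative settings were fixed before the data were examined. The plan assumed counts, normalized or log values, and the recovery replaced it. The 4 comparisons, out of 15 possible pairs of libraries, and the lists each leads with were chosen after list levels per library had been seen, as were the recovery, the thinning depth, the use of thinned shares in the 25% rule and the threshold of 1% for cells rich in a gene set. That set held pseudocounts of 1 and 100, median-ratio factors per cell, members counted in 10% of cells, leaving out the 25% of cells with fewest genes, averaging log values over cells, and other thresholds for shares. Added later were the mean of per-cell levels, thinned cells, leaving out the deepest 10% of cells, each gene's highest cell or the cells rich in neutrophil genes, unthinned shares and the difference of mean deposited scores. Random lists were also drawn for mean per-cell levels, averaged log values and levels without each gene's highest cell. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.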

Results

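Transcripts were counted in 497 single cells of the mouse haematopoietic stem and progenitor compartment by a modified Smart-seq2 method, a plate-based protocol that copies the RNA of 1 sorted cell, here with enrichment of the 3' ends. The cells came from C57BL/6 mice and were spread over 6 libraries, each of which mixed 2 or 4 sorted populations. The populations carried the names HSC1, HSC2 (haematopoietic stem cells), HPC1 (haematopoietic progenitor cells), MPP2 and MPP4 (multipotent progenitors), and most were divided further by the surface proteins CD201 and CD48. The double-negative library held CD201-CD48- HSC1 and HPC1 (76 cells). The HSC1 library held CD201+CD48- and CD48+ HSC1 (84 cells), and the HPC1 library held the same gates of HPC1 (82 cells); both carried a spleen label, while the other 4 were labelled bone marrow. The MPP2-containing library held MPP2 together with CD201-CD48- HPC1, CD48+ HSC1 and CD48+ HPC1 (80 cells). The HSC2/MPP4 library held CD48+ HSC2 and MPP4 (89 cells), and the CD48-negative HSC2 library held CD201+ and CD201- cells of that gate (86 cells). Cells could be traced to a library but not to a population within it, so every comparison is between libraries. There was 1 library per group, so no difference has a replicate check and none was tested.

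Median counts per cell were 105223 in the double-negative, 63091 in the HSC1, 112830 in the HPC1, 145494 in the MPP2-containing, 35976 in the HSC2/MPP4 and 23540 in the CD48-negative HSC2 library. Library totals ran from 2778804 counts in CD48-negative HSC2 to 15019256 in the MPP2-containing library. Levels are pooled counts per 1000000 counts (CPM) with exact 95% Poisson intervals, and shares of cells are taken after thinning each cell to 10000 counts, with exact Clopper-Pearson intervals. Both kinds of interval cover counting error only. Amplified reads need not be independent molecules, so the intervals can be too narrow even for that. They leave out the spread between cells. Among HPC1 cells not rich in megakaryocyte-platelet genes, the variance of Pf4 was 223 times that of counting error. The median was 27.3 times for genes of like level. Ratios are log2 values with 10 CPM added to each side, which understates the difference of genes at low level. The median log2 ratio over all 11985 genes lay between -0.04 and 0.00 in the 4 comparisons.

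The genes of the sorted surface proteins were examined first. Cd48 stood at 1.62 CPM (0.925 to 2.63) in the double-negative library and 9.36 (6.11 to 13.7) in CD48-negative HSC2, where 1 cell held 61.5% of its counts. It reached 33.9 in HPC1, 81.4 in HSC1, 122 in the MPP2-containing and 173 (160 to 187) in the HSC2/MPP4 library. Procr, which encodes CD201, was highest in HSC1 at 133 (125 to 142) and CD48-negative HSC2 at 115 (102.9 to 128), followed by HPC1 at 71.6. It was lower in the double-negative library at 23.9, in HSC2/MPP4 at 17.8 and in the MPP2-containing library at 16.4. Itga2b, the gene of CD41, stood at 255 (246 to 264) in HPC1 against 55.5 (49.9 to 61.5) in HSC1. Slamf1, the gene of CD150, ranged from 22.9 to 43.6 in the 4 libraries without HSC2, whereas all 8 counts in HSC2/MPP4 came from 1 cell and CD48-negative HSC2 had 0 counts, which allows up to 1.08 CPM. Flt3, the receptor of a cytokine that acts on multipotent and lymphoid progenitors, stood at 286 in HSC2/MPP4 and 156 in CD48-negative HSC2 and at 34.2 or less in the other libraries. After thinning, Cd48 was counted in 1.3% of double-negative cells (1 of 75, interval 0.0 to 7.2%) and 58.0% of HSC2/MPP4 cells (47 of 81, 46.5 to 68.9%). On the reference genome GRCm38 (mm10), Cd48 spans 171682009 to 171705258 on the plus strand of chromosome 1 and Procr 155751117 to 155755471 on the plus strand of chromosome 2; both are protein-coding.

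**Figure D1:**
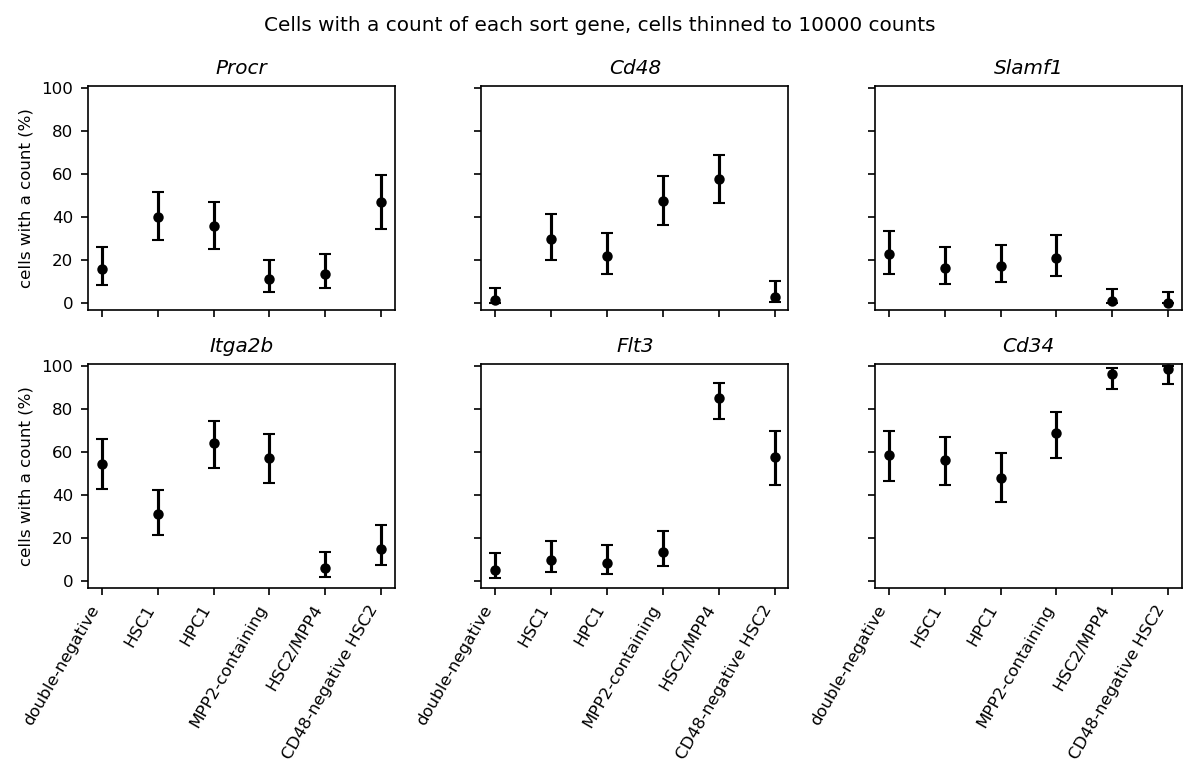
Share of cells with at least 1 count of 6 surface-protein genes (panels) in each of the 6 libraries (x axis), in percent of cells thinned to 10000 counts (y axis); bars show exact 95% Clopper-Pearson intervals, counting error only. Cd48 was counted in 1.3% of double-negative and 3.0% of CD48-negative HSC2 cells, and Flt3 in 85.2% of HSC2/MPP4 cells.

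The HPC1 library was set against the HSC1 library, since the same CD201 and CD48 gates were mixed in both. Cells could not be traced to a gate, so a different mix of gates cannot be told apart from a difference between HPC1 and HSC1. Both gate genes were lower in HPC1, Cd48 at 33.9 against 81.4 CPM and Procr at 71.6 against 133. Megakaryocyte and platelet genes were higher in HPC1. The list median was 1.18 on the log2 scale, at percentile 100 of 10000 random lists matched on level, and 13 of 22 members were at least 2-fold higher and 0 were 2-fold lower. Pf4, a chemokine stored in platelet granules, stood at 2709 CPM (2679 to 2740) against 102.9 (95.3 to 111), and Gp1bb, a subunit of the platelet receptor for von Willebrand factor, at 175 (167 to 182) against 5.55 (3.88 to 7.68). Vwf itself was at 64.3 against 21.6. Nfe2, also on the list, differed little, with a log2 ratio of -0.07.

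Cell-cycle genes were moderately higher in HPC1. All 21 S phase genes had a ratio above 0, with a median of 0.55, and 19 of 20 G2/M genes did, with a median of 0.71; both medians lay at percentile 100. Mki67, a marker of proliferating cells, stood at 199 against 85.2 CPM and Top2a at 385 against 230. The erythroid list had a median of 0.57 (percentile 100), with 5 of 18 members 2-fold higher and 1 lower. The higher members included the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, whereas Car1, an erythroid carbonic anhydrase, was lower (13.6 against 146 CPM). The mature neutrophil list had the largest median of the 20 lists measured, 3.92 (percentile 100), with Lcn2, Camp, Ngp, Ltf, S100a8 and S100a9 all over 2-fold higher.

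Lymphoid progenitor genes were slightly lower in HPC1 in pooled counts. The list had a median of -0.27 (percentile 0.52), with Flt3, Dntt, Satb1 and Cd27 among the members at least 2-fold lower of 15. Among the single genes with the lowest ratios, Tespa1, a T cell receptor signalling gene, gave -3.18, Plac8 -2.01, the transcription factor gene Sox4 -1.86, Impact -1.71 and Lgals1 -1.59. Tgoln1 gave -1.55, Ralgps2 -1.44, Csf3r, the receptor of granulocyte colony-stimulating factor, -1.39 and Emb -1.39. Cavin2 was higher at 2.84. HSC genes had a median of -0.33 (percentile 0.23), with Ly6a (-1.20), Hlf (-0.98), Mllt3 (-0.90) and Procr (-0.81) lower and Nupr1 (0.81) and Esam (0.71) higher. The granulocyte-monocyte progenitor list had a median of 0.01 (percentile 31.2).

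Single cells set the size of some of these differences. Without 3 HPC1 cells in which neutrophil genes made up 1% or more of the counts, the neutrophil median was 1.48. Without each gene's highest cell, Lcn2 went from 4.78 to 2.32, Camp from 4.63 to 2.55, Ngp from 4.37 to 1.97, Ltf from 4.23 to 1.09, S100a9 from 3.61 to 2.35, S100a8 from 2.96 to 2.29, Hba-a2 from 3.31 to 1.73, Hba-a1 from 2.94 to 1.92 and Hbb-bt from 1.82 to 0.49, no longer 2-fold, while Pf4 stayed at 4.56. The least S100a8, Hbb-bs and Pf4 counts in any HPC1 cell were 13, 12 and 14, so the shares of HPC1 cells with these transcripts were not read as shares of expressing cells. In HPC1, 3 cells held 66.6% of the haemoglobin counts, whose sum was 4460 CPM, or 1532 without them, against 678 in HSC1. Hba-a1 and Hba-a2 are near-identical copies whose reads cannot be told apart with certainty. The HSC list had no firm direction, since its median was 0.13 when log values were averaged over cells and 0.01 in the deposited scores; the lymphoid median was 0.00 in those scores.

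**Figure D2:**
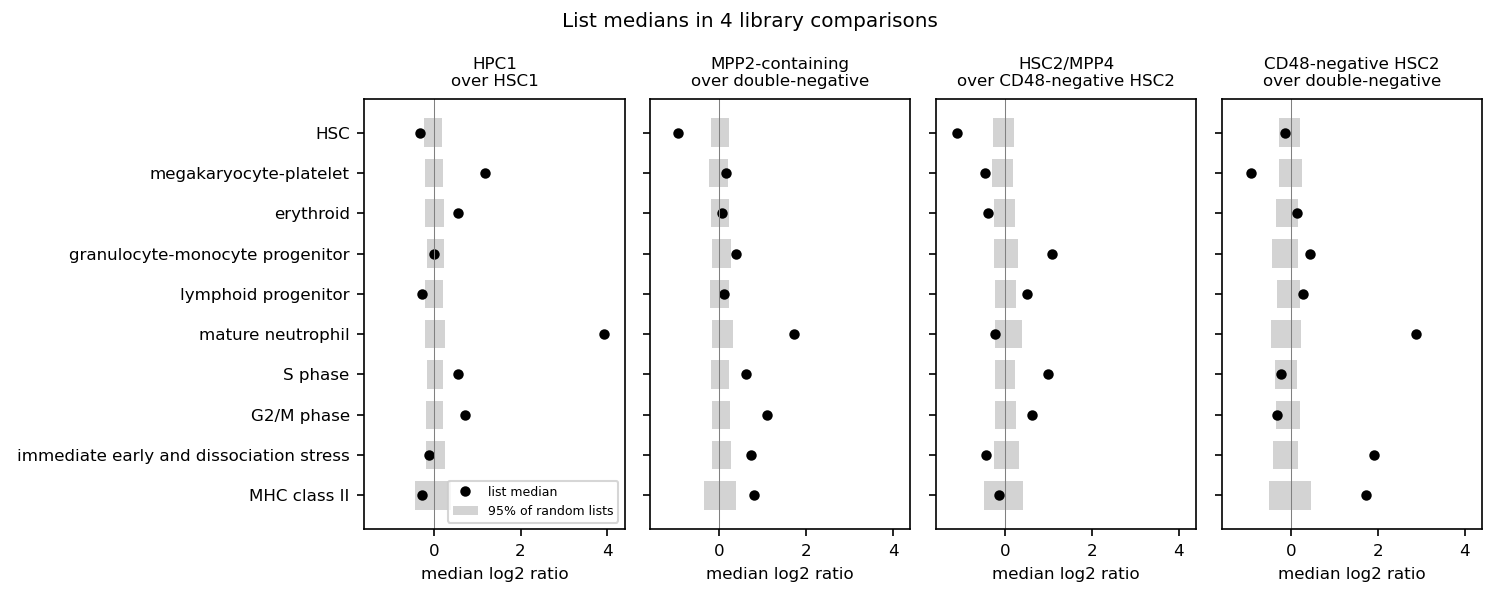
Median log2 ratio of 10 gene lists (y axis) in the 4 library comparisons (panels), with grey bars for the central 95% of 10000 random lists of the same size matched on level; log2 scale, 10 CPM added (x axis). The megakaryocyte-platelet median was 1.18 in HPC1 over HSC1 and -0.92 in CD48-negative HSC2 over double-negative.

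The MPP2-containing library was set against the double-negative library, both from bone marrow and sharing 1 sorted population, CD201-CD48- HPC1. HSC genes were lower in the MPP2-containing library. The list median was -0.95 (percentile 0.00), 10 of 23 members were at least 2-fold lower and 0 were 2-fold higher. Mecom and Mllt3, regulators of stem cell maintenance, gave -1.43 and -1.42, at 46.1 (42.8 to 49.7) against 142 (134 to 149) and 56.4 (52.7 to 60.3) against 168 (160 to 176) CPM. Ly6a gave -1.09 and Nupr1 -1.74. Mecom lies on the minus strand of chromosome 3 from 29951296 to 30548008.

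Proliferation genes were higher in the MPP2-containing library. All 20 G2/M genes had a ratio above 0, with a median of 1.10 (percentile 100) and 11 at least 2-fold higher, among them Tpx2 (1.70), Bub1 (1.66) and Top2a (1.52). S phase genes had a median of 0.62 (percentile 100), with 7 of 21 at least 2-fold higher, such as Rrm2 (1.79) and Tyms (1.39). Pclaf, a partner of the replication clamp PCNA, gave 2.43, or 3.06 without its highest cell in each library, and the histone gene Hist1h2ae, one of many similar copies, 2.19.

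Some genes of granulocyte and monocyte progenitors were higher in pooled counts. The list median was 0.38 (percentile 99.9), but inside the random range at 0.20 (percentile 92.1) with mean per-cell levels, 0.23 (92.7) without each gene's highest cell and 0.14 (43.5) with averaged log values. Of 18 members 6 were at least 2-fold higher in pooled counts and 1, Irf8 (-1.08), was lower. Mpo, Elane and Ctsg, which encode neutrophil granule enzymes, gave 4.41, 4.45 and 4.57, and Elane 3.76 without its highest cell. In this library 2 cells held 84.0% of the counts of these 3 genes, and without them their sum was 226 CPM against 31.5 in the double-negative library. Low counts of Mpo, S100a8 and Pf4 were present in all 80 MPP2-containing cells (at least 1, 9 and 2), as S100a8, Hbb-bs and Pf4 were in HPC1, and in the remaining cells Elane varied less than nearly all genes of like level (percentile 1), while Mpo and Ctsg varied more than most (both 99). Cd48, the gene of a sorted protein, gave 3.50, Car1 3.07, Tespa1 3.07, Cd69 2.27 and Nkg7 2.13. On the lower side were Insr (-1.64), Fam110c (-1.59), Phlda2 (-1.48), Sox6 (-1.43), Grb10 (-1.41), Selenom (-1.32), Smim6 (-1.32) and Ccdc28a (-1.31). The megakaryocyte-platelet list had a median of 0.16 (percentile 95.6), inside the range of random lists in pooled counts but outside it at 0.20 (98.7) with mean per-cell levels and 0.26 (98.9) without each gene's highest cell, with Plek and Pf4 2-fold higher and Mmrn1 among the members 2-fold lower. The neutrophil median was 1.72, or 0.56 without the cells rich in neutrophil genes (3 in the MPP2-containing and 1 in the double-negative library). Averaging log values over cells reduced the HSC median to -0.43.

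The HSC2/MPP4 library was set against the CD48-negative HSC2 library, which contrasts CD48+ HSC2 and MPP4 with CD48-negative HSC2 within 1 deposit. HSC genes were lower in HSC2/MPP4, with a median of -1.11 (percentile 0.00) and 14 of 23 members at least 2-fold lower. Mecom was at 64.7 (57.0 to 73.2) against 223 (206 to 241) CPM and Mllt3 at 20.6 against 104. Procr, at 17.8 against 115, encodes CD201, by which, of the 2 libraries, only CD48-negative HSC2 was sorted, so the gate can set part of its difference. Ltb gave -2.36, Pdzk1ip1 -2.24 and Esam -2.10.

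Granulocyte-monocyte progenitor and lymphoid progenitor genes were higher in HSC2/MPP4 in pooled counts. The granulocyte-monocyte progenitor list had a median of 1.09 (percentile 100), with 9 of 18 members at least 2-fold higher and 1, Lyz2 (-1.34), lower. Mpo gave 6.46 and 5.68 without its highest cell, and Irf8, a transcription factor of monocyte and dendritic cell development, 3.46. The lymphoid progenitor list had a median of 0.50 (percentile 100), with Dntt, Il12a and Satb1 at least 2-fold higher among 15. Dntt, the polymerase that adds nucleotides at antigen receptor junctions, stood at 554 CPM (532 to 578) against 25.9 (20.3 to 32.6); it lies on the plus strand of chromosome 19 from 41029275 to 41059525. It was counted in 59.3% of HSC2/MPP4 and 7.6% of CD48-negative HSC2 cells after thinning. Ighm, the immunoglobulin mu heavy chain gene, gave 2.75.

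All 21 S phase and all 20 G2/M genes had a ratio above 0, with medians of 0.98 and 0.62 (both percentile 100). Megakaryocyte-platelet genes had a median of -0.48 (percentile 0.03) and 8 of 22 were at least 2-fold lower, such as Gp9 (-2.03) and Pf4 (-1.87). The erythroid median was -0.39 (percentile 0.17), led by the 4 haemoglobin genes, of which Hbb-bt gave -3.13; 1 CD48-negative HSC2 cell held 76.3% of that library's haemoglobin counts, whose sum was 2692 CPM, or 640 without 2 rich cells, against 175 in HSC2/MPP4. In contrast, Car1 gave 4.50 and Klf1 1.08. Other named genes were Cst7 (4.11), the sort gene Cd48 (3.24), Clec12a (2.92), Nkg7 (2.5), Ccl9 (2.29) and Cnn3 (2.23) on the higher side. Hacd4 (-2.88), Nceh1 (-1.98), Cuedc1 (-1.87) and Hmox1 (-2.24, or -1.38 without its highest cell) were on the lower side. In CD48-negative HSC2, 1 cell was the highest for all 20 G2/M genes and held 53.8% of their counts, and without each gene's highest cell the G2/M median was 1.82. The granule genes Mpo, Elane and Ctsg had 94.6% of their HSC2/MPP4 counts in 4 cells, without which their sum was 454 CPM against 33.5, and averaging log values over cells reduced the granulocyte-monocyte median to 0.38 (percentile 90.7), inside the random range.

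The CD48-negative HSC2 library was set against the double-negative library, which contrasts HSC2 with HSC1 and HPC1 among cells sorted without CD48; the former held CD201+ and CD201- cells and the latter CD201- cells alone. Megakaryocyte-platelet genes were lower in HSC2, with a median of -0.92 (percentile 0.00) and 11 of 22 members at least 2-fold lower. Pf4 was at 69.5 (60 to 80) against 332 (321 to 344) CPM, Gp5 gave -2.62 and Gata1, a transcription factor of megakaryocyte and erythroid cells, stood at 1.08 (0.223 to 3.15) against 60.5 (55.7 to 65.5). Lymphoid progenitor genes were slightly higher, with a median of 0.28 (percentile 99.2) and Flt3 (2.73), Dntt (1.80), Satb1, Ikzf1 and Lsp1 at least 2-fold higher, though without each gene's highest cell the median was 0.12 (percentile 96.5), inside the random range.

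HSC genes did not stand apart as a list in pooled counts, with a median of -0.13 (percentile 29.1). Their median was lower in other settings, at -0.30 (percentile 3.12), still inside the random range, with mean per-cell levels. It was -0.48 without the deepest 10% of cells, a setting without random lists of its own. Members went both ways, with Ltb (3.47), Procr (1.89), Ly6a (1.67) and Hlf (1.18) higher and Nupr1 (-2.95), Slamf1 (-1.87), Ctnnal1 (-1.68), Pdzk1ip1 (-1.14) and Sult1a1 (-1.07) lower. S phase and G2/M medians were -0.23 (percentile 20.8) and -0.33 (percentile 3.24) in pooled counts; the G2/M median lay outside the random range at -0.95 with mean per-cell levels and -1.0 without each gene's highest cell (both percentile 0.00). Immediate early genes, which respond within minutes to stimulation or handling, were higher in CD48-negative HSC2, with a median of 1.91 (percentile 100) and 8 of 10 members at least 2-fold higher. Nr4a1 stood at 394 (371 to 418) against 7.69 (6.06 to 9.62) CPM and Fos at 2212 against 311. MHC class II genes, of antigen presentation, had a median of 1.72 (percentile 100), with Cd74 at 3.31. With mean per-cell levels the median was 1.62 (percentile 100). The share of thinned cells with counts of the list was similar, at 45.5% in CD48-negative HSC2 and 42.7% in the double-negative library. In CD48-negative HSC2, 1 cell held 24.8% of the list's counts.

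The chemokine genes Ccl3 and Ccl4 gave 4.35 and 3.06, Wfdc17 3.68, Rgs1 3.21, Hes1, a target of Notch signalling, 3.20, Tespa1 3.19 and Myl10 3.0. Lower were Cavin2 (-3.04), Apoe (-2.37), Hist1h4n (-2.32), Aldh1a1 (-2.19), Selenom (-1.98), Pdcd4 (-1.92), Rpp38 (-1.91) and Tpp1 (-1.89). Apoe, a lipid carrier protein gene, was at 243 (225 to 262) against 1303 (1281 to 1326) CPM. Without the cells rich in neutrophil genes, 1 in each library, the neutrophil median went from 2.88 to 0.02 and the granulocyte-monocyte progenitor median from 0.43 to 0.01. The libraries also differed in deposit, RNA label and age range, so HSC2 identity, the CD201 gate and batch cannot be told apart here.

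Mitochondrial transcripts, used as a sign of RNA quality, could be followed in 2 of the 9 mitochondrial genes in the data. Genes counted in nearly every cell could not be recovered, so these 2 need not stand for mitochondrial RNA as a whole. mt-Atp6 was at or near 0, with 27 counts in the MPP2-containing library, 1 in each HSC2 library and 0 in the others. mt-Nd3 stood at 4.15 CPM in the double-negative and 10.0 in the HSC1 library, against 178 in HPC1, 464 in the MPP2-containing, 330 in HSC2/MPP4 and 275 in CD48-negative HSC2. mt-Nd3 was therefore higher in the first-named library of every comparison, with a log2 ratio of 0.25 in HSC2/MPP4 over CD48-negative HSC2 and 3.23, 5.07 and 4.33 in the others.

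Transcripts of mature neutrophils were concentrated in few cells in every library but HSC1. The neutrophil list made up 1% or more of the counts in 1 double-negative, 0 HSC1, 3 HPC1, 3 MPP2-containing, 1 HSC2/MPP4 and 1 CD48-negative HSC2 cell. The highest cell held 31.4% neutrophil counts in HSC2/MPP4 and at least 30.2% in CD48-negative HSC2, where 2 of its values for the list were capped. In HSC2/MPP4 the list's summed level was 5199 CPM with that cell and 57.0 without it, and in HPC1 it was 4374 with the 3 cells and 1187 without them. Of the thinned cells below 1%, 100% in HPC1 and 96.1% in the MPP2-containing library still held counts of the list. In the other libraries 28.7 to 63.5% did.

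**Figure D3:**
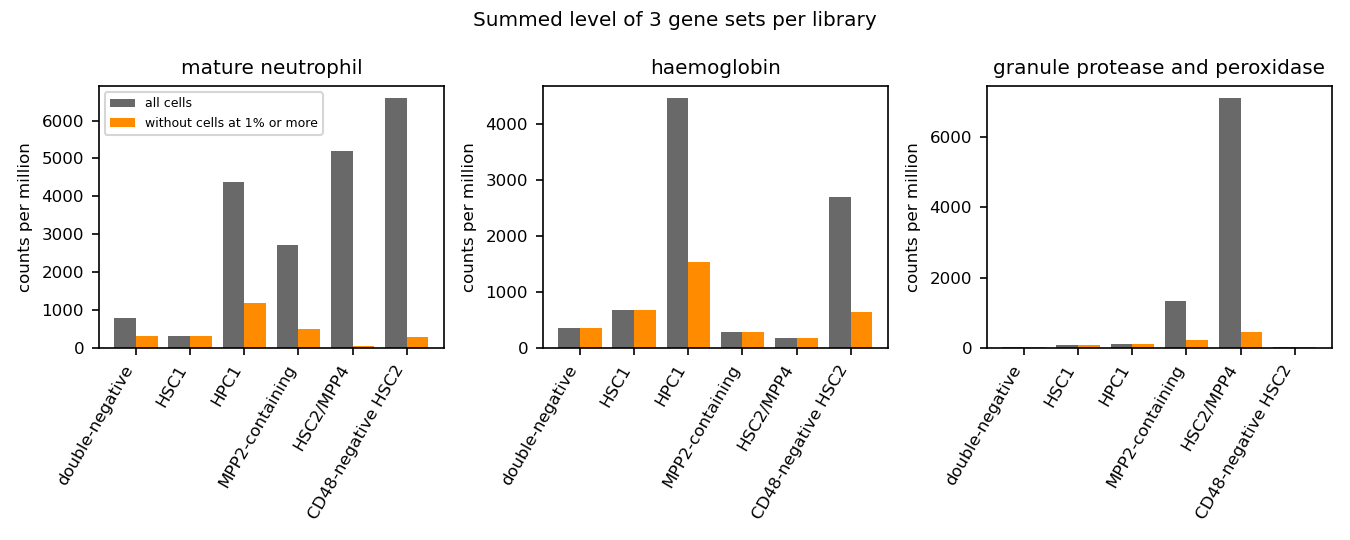
Summed level in CPM (y axis) of 3 gene sets (panels: mature neutrophil list, haemoglobin genes, and Mpo, Elane and Ctsg) in each of the 6 libraries (x axis), over all cells and without the cells in which the set makes up 1% or more of the counts. The neutrophil sum in HPC1 was 4374 with all cells and 1187 without 3 cells, and the haemoglobin sum in HPC1 was 4460 and 1532.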

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

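The tests on few cells, on depth, on single cells, on batch and on the dispersion of megakaryocyte-platelet genes were chosen after the result was seen; the dispersion test of neutrophil genes was set before its result. Immediate early and dissociation stress genes went in opposite directions in 2 comparisons of a library that held CD48+ cells with one sorted without CD48. These are not the same contrast, since the MPP2-containing library also held CD201-CD48- HPC1, a population of the double-negative library. The list median was 0.72 in MPP2-containing over double-negative and -0.44 in HSC2/MPP4 over CD48-negative HSC2. The difference between these was not tested, and the second value went to 0.03 without the deepest 10% of cells and to -0.23 (percentile 2.98), inside the random range, with mean per-cell levels.

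Mature neutrophil genes were higher in the HPC1 than in the HSC1 library, by a list median of 3.92. A few cells with very high neutrophil transcripts do not account for all of it, since the median was 1.48 without 3 such cells, still above the random range. RNA of such cells spread evenly over the others stays open: the median dispersion percentile of 6 members among genes of like level was 45.5, between the bounds set for and against it, with Lcn2, Ltf and Ngp at 1, 2 and 3 and S100a9, S100a8 and Camp at 88, 89 and 95. In the remaining cells S100a8 made up 57.2 to 65.1% of the counts of these 6 members in all 6 libraries, a mix seen after the test. Outside the list, Mpo, Elane and Ctsg were at percentiles 0, 1 and 0 in HPC1, below the bound set for even spread of the neutrophil list. Mpo had at most 30 counts in an HPC1 cell, and 7 of 82 cells had 0. The haemoglobin genes had a median percentile of 28.5 in HPC1, against 98.5 to 100 in the other libraries. These genes had no test of their own. No sort in the labels names a neutrophil marker, and expression of the genes by HPC1 cells themselves was not tested.

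Megakaryocyte-platelet genes were higher in HPC1 than in HSC1, by a median of 1.18. The median was 1.11 after thinning, which cannot decide whether a difference in depth plays a part. Levels are already scaled to total counts, and thinning leaves a gene's expected share of a cell's counts unchanged. The tables argue against a single cell per gene as the whole cause, with 1.21 without the highest cells. RNA spread evenly from a few cells stays open: without the 8 HPC1 cells in which the list made up 1% or more of the counts, the median dispersion percentile of 21 members was 46, between the bounds set for and against it, with Fli1, Plek and Nfe2 at 8, 14 and 16 and Itga2b, Gp1bb and Gp9 at 92, 93 and 96. A difference between HPC1 and HSC1 cells in this programme is a candidate explanation that no replicate tests. A difference between the 2 libraries in the mix of CD201 and CD48 gates or in handling stays open too. The 8 cells held 46.6% of the list's counts, and without them its sum was 3318 against 1297 CPM in HSC1.

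Immediate early genes were higher in both HSC2 libraries than in the earlier ones. A single cell per gene is argued against, since the median of CD48-negative HSC2 over double-negative was 1.90 without each gene's highest cell. Of 10 members, 8 were higher in both HSC2 libraries than in each of the 4 others, as a difference in library batch, RNA label or handling could give. The same 2 libraries hold all HSC2 and MPP4 cells and carry another RNA label, so batch and cell identity cannot be told apart, and biology stays open as untested.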

How the results depend on the processing

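The settings reported here for thinned cells, the deepest cells, each gene's highest cell, the cells rich in neutrophil genes, mean per-cell levels, deposited scores and unthinned shares were chosen after the result was seen; the others were set before the data were examined. Of 37 list medians outside the random range, 29 kept their sign in all settings run. The 8 others were HSC and lymphoid genes in HPC1 over HSC1, mature B, T and NK cell genes in MPP2-containing over double-negative, mast cell-basophil, immediate early and interferon genes in HSC2/MPP4 over CD48-negative HSC2, and granulocyte-monocyte and neutrophil genes in CD48-negative HSC2 over double-negative. Each of these went to 0.00 or to the other sign in at least 1 setting. The settings that weigh single cells differently were given random lists of their own, after the result was seen, and 25 of the 37 kept their sign and stayed outside the range in all of them (33 with mean per-cell levels, 27 with averaged log values and 30 without each gene's highest cell). Of 43 list medians inside the range, 13 were outside it in at least 1 of these settings. Of the 16 list medians that lead the comparisons, 87 of 176 log2 values under other settings lay within 1 SD of random-list medians of the main value, 88 lay further away with the sign kept or no call made, and 1 turned the sign. Of the other 64 list medians, 459 of 693 log2 values lay within that distance, 231 did not and 3 turned the sign. The deposited scores have another unit, so only signs were compared, which were those of the log2 medians for 14 of the 16 and 47 of the 64. A larger pseudocount pulls ratios of low genes toward 0 by construction. Leaving out a gene's highest cell can move most the genes with much of their counts in that cell, but changes others too. For the other settings the cause was not tested. Setting genes with 0 counts at 3 counts moved no list median by more than 0.15. The comparisons of sorted populations, of the same population in 2 libraries and of 1 library at a time were not run, because cells could not be assigned to populations. No paired analysis was possible because each group is 1 library. Depth limits low genes most in CD48-negative HSC2, with 23540 counts per cell at the median.

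The values that moved are given by setting, as log2 list medians, for the lists that lead the comparisons. Of the other lists, only values whose sign turned are included. Adding 1 CPM gave 1.60 (megakaryocyte-platelet) for HPC1 over HSC1. Adding 1 CPM gave -1.08 (HSC), 0.33 (megakaryocyte-platelet) and 1.16 (granulocyte-monocyte) for MPP2-containing over double-negative. Adding 1 CPM gave -1.77 (HSC), 1.59 (granulocyte-monocyte) and 0.88 (lymphoid) for HSC2/MPP4 over CD48-negative HSC2. Adding 1 CPM gave -0.27 (HSC), -1.42 (megakaryocyte-platelet) and 0.60 (lymphoid) for CD48-negative HSC2 over double-negative. Adding 100 CPM gave -0.12 (HSC), 0.43 (megakaryocyte-platelet) and 0.35 (G2/M) for HPC1 over HSC1. Adding 100 CPM gave -0.28 (HSC), 0.03 (megakaryocyte-platelet), 0.08 (granulocyte-monocyte) and 0.61 (G2/M) for MPP2-containing over double-negative. Adding 100 CPM gave -0.33 (HSC), 0.24 (granulocyte-monocyte), 0.07 (lymphoid) and 0.36 (G2/M) for HSC2/MPP4 over CD48-negative HSC2. Adding 100 CPM gave -0.32 (megakaryocyte-platelet), 0.03 (lymphoid) and -0.17 (G2/M) for CD48-negative HSC2 over double-negative. Median-ratio scaling gave -0.13 (HSC), 1.05 (megakaryocyte-platelet) and 0.16 (granulocyte-monocyte) for HPC1 over HSC1. Median-ratio scaling gave -0.74 (HSC) and 0.17 (granulocyte-monocyte) for MPP2-containing over double-negative. Median-ratio scaling gave 0.78 (granulocyte-monocyte) and 1.61 (G2/M) for HSC2/MPP4 over CD48-negative HSC2. Median-ratio scaling gave -0.43 (HSC), -1.14 (megakaryocyte-platelet) and -1.03 (G2/M) for CD48-negative HSC2 over double-negative. Members counted in 10% of cells gave 0.28 (megakaryocyte-platelet) and 0.50 (granulocyte-monocyte) for MPP2-containing over double-negative. Members counted in 10% of cells gave -1.56 (HSC) and 1.61 (granulocyte-monocyte) for HSC2/MPP4 over CD48-negative HSC2. Members counted in 10% of cells gave -0.40 (HSC), -1.29 (megakaryocyte-platelet) and 0.80 (lymphoid) for CD48-negative HSC2 over double-negative. Averaged log values gave 0.13 (HSC) and 1.06 (megakaryocyte-platelet) for HPC1 over HSC1. Averaged log values gave -0.43 (HSC), 0.14 (granulocyte-monocyte) and 1.55 (G2/M) for MPP2-containing over double-negative. Averaged log values gave -0.56 (HSC), 0.38 (granulocyte-monocyte), 1.04 (G2/M) and 0.12 (interferon) for HSC2/MPP4 over CD48-negative HSC2. Averaged log values gave -0.33 (HSC), 0.05 (lymphoid), -0.29 (neutrophil) and -0.74 (G2/M) for CD48-negative HSC2 over double-negative. Mean per-cell levels gave -0.20 (HSC), 1.0 (megakaryocyte-platelet) and 0.14 (granulocyte-monocyte) for HPC1 over HSC1. Mean per-cell levels gave -0.74 (HSC), 0.20 (granulocyte-monocyte) and 1.22 (G2/M) for MPP2-containing over double-negative. Mean per-cell levels gave 0.62 (granulocyte-monocyte) and 1.54 (G2/M) for HSC2/MPP4 over CD48-negative HSC2. Mean per-cell levels gave -0.30 (HSC) and -0.95 (G2/M) for CD48-negative HSC2 over double-negative. Thinned cells gave 0.18 (granulocyte-monocyte) for HPC1 over HSC1. Thinned cells gave -0.53 (HSC), 0.37 (megakaryocyte-platelet) and 0.25 (granulocyte-monocyte) for MPP2-containing over double-negative. Thinned cells gave -1.26 (HSC), 0.84 (granulocyte-monocyte) and 1.38 (G2/M) for HSC2/MPP4 over CD48-negative HSC2. Thinned cells gave 0.49 (lymphoid) and -0.64 (G2/M) for CD48-negative HSC2 over double-negative. Leaving out the deepest 10% of cells gave -0.18 (HSC), 1.01 (megakaryocyte-platelet) and 1.16 (G2/M) for HPC1 over HSC1. Leaving out the deepest 10% of cells gave 0.76 (granulocyte-monocyte), 1.62 (G2/M) and 0.03 (immediate early) for HSC2/MPP4 over CD48-negative HSC2. Leaving out the deepest 10% of cells gave -0.48 (HSC), -1.16 (megakaryocyte-platelet) and -1.11 (G2/M) for CD48-negative HSC2 over double-negative. Leaving out each gene's highest cell gave -0.19 (HSC), 0.10 (granulocyte-monocyte) and 0.84 (G2/M) for HPC1 over HSC1. Leaving out each gene's highest cell gave -0.68 (HSC), 0.23 (granulocyte-monocyte) and 1.40 (G2/M) for MPP2-containing over double-negative. Leaving out each gene's highest cell gave 0.84 (granulocyte-monocyte) and 1.82 (G2/M) for HSC2/MPP4 over CD48-negative HSC2. Leaving out each gene's highest cell gave 0.12 (lymphoid) and -1.0 (G2/M) for CD48-negative HSC2 over double-negative. The deposited scores are differences in units of each gene's SD. The deposited scores gave 0.01 (HSC), 0.47 (megakaryocyte-platelet), 0.03 (granulocyte-monocyte) and 0.10 (G2/M) for HPC1 over HSC1. The deposited scores gave -0.23 (HSC), 0.07 (megakaryocyte-platelet), 0.11 (granulocyte-monocyte) and 0.59 (G2/M) for MPP2-containing over double-negative. The deposited scores gave -0.34 (HSC), 0.23 (granulocyte-monocyte), 0.30 (lymphoid) and 0.44 (G2/M) for HSC2/MPP4 over CD48-negative HSC2. The deposited scores gave -0.16 (HSC), -0.23 (megakaryocyte-platelet), 0.06 (lymphoid) and 0.02 (G2/M) for CD48-negative HSC2 over double-negative.

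With 1 or more G2/M genes, the share of cells past the G2/M threshold was 100% in double-negative, 97.5% in HSC1, 100% in HPC1, 98.8% in HSC2/MPP4 and 86.4% in CD48-negative HSC2. With 3 or more G2/M genes, the share of cells past the G2/M threshold was 69.3% in double-negative, 85.2% in HPC1, 63.0% in HSC2/MPP4 and 28.8% in CD48-negative HSC2. With 2 or more S phase genes, the share was 97.3% in double-negative, 98.8% in HSC1, 100% in HPC1, 100% in HSC2/MPP4 and 93.9% in CD48-negative HSC2. With 2 counts or more, the share with Procr was 26.2% in HSC1, 2.5% in MPP2-containing and 30.3% in CD48-negative HSC2. With 2 counts or more, the share with Cd48 was 0.0% in double-negative (0 of 75 cells, which allows up to 4%), 17.5% in HSC1, 7.4% in HPC1, 27.5% in MPP2-containing and 38.3% in HSC2/MPP4. Without thinning, the share of cells past the G2/M threshold was 100% in double-negative, 100% in HSC1 and 100% in HPC1. Without thinning, the share with Procr was 43.4% in double-negative, 75% in HSC1, 58.5% in HPC1, 36.2% in MPP2-containing and 27.0% in HSC2/MPP4. Without thinning, the share with Cd48 was 15.8% in double-negative, 48.8% in HSC1, 45.1% in HPC1, 82.5% in MPP2-containing and 70.8% in HSC2/MPP4. Without the 25% of cells with fewest genes, the share of cells past the G2/M threshold was 100% in HPC1.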

Other observations

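Everything here was examined after the data had been seen, apart from the fixed gene lists. The MHC class II list was 0.80 in MPP2-containing over double-negative (percentile 100), -0.28 in HPC1 over HSC1 (7.95) and -0.15 in HSC2/MPP4 over CD48-negative HSC2 (25.5). The first was 0.22 (percentile 61.3) with averaged log values, and the last has no firm direction, at 1.03 (99.99) with mean per-cell levels and -0.46 (1.52) without each gene's highest cell. The HPC1 value was outside the random range at -0.46 (0.64) without each gene's highest cell. In HSC2/MPP4, 2 cells held 65.1% of its counts, and its sum was 458 CPM with them and 161 without. Ccl3 stood at 249 CPM in HSC2/MPP4 and 309 in CD48-negative HSC2, against 65.6 in the MPP2-containing library and 14.8 or less in the others. Apoe showed the reverse, at 94.8 and 243 in the 2 HSC2 libraries and 1303 to 1619 in the other 4.

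Ribosome biogenesis and Myc target genes were higher in HSC2/MPP4 than in CD48-negative HSC2 (0.42, percentile 99.8), as were mitochondrial respiration genes (0.39, 98.9) and mast cell-basophil genes (0.56, 99.9), while interferon response genes were at -0.48 (0.39). The interferon median had no firm direction, at -0.19 (percentile 14.4) with mean per-cell levels and 0.12 (19.0) with averaged log values. Mast cell-basophil genes were at 0.04 (73.7) without each gene's highest cell, and ribosome biogenesis genes at 0.62 (96.6), inside the random range, with averaged log values. In the other comparisons ribosome biogenesis gave 0.08, 0.06 and -0.16, mitochondrial respiration 0.16, 0.23 and -0.29, and interferon response -0.21, -0.17 and 0.14, for HPC1 over HSC1, MPP2-containing over double-negative and CD48-negative HSC2 over double-negative in this order, all inside the random range in pooled counts. Outside it were ribosome biogenesis at 0.49 (percentile 98.8) and interferon response at -0.04 (1.68) in MPP2-containing over double-negative with averaged log values, and mitochondrial respiration at 0.27 (98.2) in HPC1 over HSC1 without each gene's highest cell. In that order mast cell-basophil genes gave -0.14, 0.53 and -0.03, with 0.53 at percentile 99.8 and 0.32 without the cells rich in neutrophil genes. Cell-cycle inhibitor and quiescence genes gave -0.26, 0.15 and 0.39, and -0.31 in HSC2/MPP4 over CD48-negative HSC2, all inside the range in pooled counts; without each gene's highest cell they were outside it at -0.38 (0.28) in HPC1 over HSC1 and 0.44 (98.3) in CD48-negative HSC2 over double-negative. Cdkn1a, an inhibitor of cyclin-dependent kinases, was 2.08 in CD48-negative HSC2 over double-negative. Immediate early genes gave -0.11 in HPC1 over HSC1 (percentile 9.81).

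Of other cell types, macrophage-monocyte genes gave 0.57 (percentile 99.97) and mature B, T and NK cell genes 0.36 (99.04), or 0.00 (45.3) without each gene's highest cell, in MPP2-containing over double-negative. In the other 3 comparisons they were inside the random range in pooled counts, at 0.07, 0.06 and 0.30 and at -0.04, -0.09 and 0.26 for HPC1 over HSC1, HSC2/MPP4 over CD48-negative HSC2 and CD48-negative HSC2 over double-negative. With mean per-cell levels macrophage-monocyte genes were outside it at 0.39 (99.4) in HSC2/MPP4 over CD48-negative HSC2 and, just past its bound, 0.42 (97.5) in CD48-negative HSC2 over double-negative. Endothelial and stromal genes were inside it in all 4 (0.03, -0.15, 0.03 and 0.09), as were glycolysis genes (0.00, 0.05, 0.21 and 0.00), here in the order HPC1, MPP2-containing, HSC2/MPP4 and CD48-negative HSC2 as the first library. Surface-protein genes gave -0.93 (percentile 0.00), 0.26, -0.28 and 1.20 (percentile 100) in that order. The HSC2/MPP4 value was outside the random range only in other settings, such as -0.34 (1.04) with mean per-cell levels. This list holds Procr and Cd48, whose proteins were sorted, so the gates can set part of its medians. Erythroid genes gave 0.06 in MPP2-containing over double-negative and 0.15 in CD48-negative HSC2 over double-negative, lymphoid genes 0.09 in the former, and neutrophil genes -0.23 (percentile 2.98) in HSC2/MPP4 over CD48-negative HSC2, or -0.97 without the cells rich in neutrophil genes, 1 in each library.

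Procr and Cd48 transcripts were rarely counted in the same cell where CD201+CD48- and CD48+ gates were mixed. Of 80 thinned HSC1 cells, 27 held Procr alone, 19 Cd48 alone, 5 both and 29 neither, with 9.6 cells expected to hold both if the genes were independent. In HPC1 the numbers were 26, 15, 3 and 37 of 81, with 6.4 expected. With all counts, 28 HSC1 cells held both against 30.7 expected and 22 HPC1 cells against 21.7, so the gap was seen only at the thinned depth.

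At least 2 G2/M genes were counted in 90.7% (81.7 to 96.2%) of double-negative, 82.5% (72.4 to 90.1%) of HSC1, 97.5% of HPC1, 100% of MPP2-containing, 82.7% of HSC2/MPP4 and 50% (37.4 to 62.6%) of CD48-negative HSC2 cells after thinning. At 82.5% or more in 5 libraries the share is close to saturated, and cycling was not read from it.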
